A study of Mus musculus with 6 samples.

How the data were processed

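RNA sequencing was done on 6 samples of cultured dorsal root ganglion (DRG) neurons from adult C57BL/6 mice, the sensory neurons whose cell bodies lie beside the spinal cord. Per the labels, the mice were 8 weeks old and female, 3 samples received PBS as the control, and 3 received recombinant oncomodulin (ONCM), a small calcium-binding protein, at 100 ng/ml for 12 hours. Total RNA was extracted with a column kit and libraries were made with an Illumina kit, per the labels' protocols, which do not say whether strand was kept. The labels call the samples biological replicates but do not name separate cultures or animals. The p-values measure the spread between these samples, part or all of which may be technical, and not a known spread between animals.

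The authors deposited 1 table of 45777 genes, identified by Entrez number and symbol, with 3 kinds of value for each of the 6 libraries. Raw read counts per gene were used for the main tests as the authors deposited them. The TPM values deposited by the authors were used as an alternative scale. The deposited FPKM columns were not used here. Columns were assigned to samples by the sample codes that the labels and the column names share. The submitters' processing notes name the genome build mm10. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here, so overlapping genes, antisense genes and near-identical gene copies may share reads in these counts. Coordinates come from a RefSeq gene table of assembly GRCm38.p6, the same assembly as mm10, matched by Entrez number for 45679 of the 45777 genes.

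Library totals ran from 53770820 to 64477014 counts. A floor of 3 counts in a library corresponds to between 0.0465 and 0.0558 CPM, the count scaled to library size, and covers counting error only, because reads without molecular identifiers are not independent molecules. Before averaging, replicates were compared by a chi-square test over genes with at least 20 counts. The statistic per degree of freedom was 2.76 to 7.09 within groups, so no pair differed by as little as sampling noise and all 6 libraries were kept.

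Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr at its defaults, libraries were scaled by TMM, dispersions were estimated with estimateDisp, and ONCM was compared with PBS by the quasi-likelihood F-test with robust fitting and no covariate. Benjamini-Hochberg adjusted p-values under 0.05 counted as passing, and "rose" and "fell" are used for genes that passed. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. CPM values are TMM-scaled and are given as mean and standard deviation (SD) with n = 3 per group. Gene lists with at least 5 tested members were compared with the other genes by camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists, and again by camera with an estimated correlation and by fry. The members of each list were also adjusted over the list alone.

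The test was checked on simulated counts drawn from the real means, library sizes and dispersions for this comparison, with 19994 genes passing the filter and 50 genes changed at each of 4 fold sizes. It recovered 62% of the 1.25-fold changes, 78% of the 1.5-fold, 78% of the 2-fold and 94% of the 4-fold, with 15 false calls (8.77% of its calls). That false share was above the adjusted p threshold of 0.05. The simulation changed a far smaller share of genes than the 48.3% called in the data. None of 20 simulated lists without change passed camera, and a list with most members raised 2-fold did. The simulation used means, library sizes and dispersions, and no correlation between genes. It therefore cannot show whether the preset correlation of 0.01 suits lists whose members vary together. Estimated correlations in the real lists ran from -0.046 for repair Schwann cell genes to 0.569 for cytosolic ribosomal protein genes.

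The groups, the tests, 35 gene lists with 881 gene names, most of the alternatives and the rule for named genes were fixed before the data were examined. The rule names Ocm and Armc10, the receptor reported for oncomodulin. It names the 10 largest rises and 10 largest falls by log2 fold change among genes that passed, had a mean of at least 1 CPM, had no overlap between the groups and carried an informative symbol. It also names up to 4 members of each list with the smallest p-values. Lists covered axon injury and regeneration, growth restraint, signalling targets, sensory neuron classes, ion channels, cytoskeleton, neurotrophic factors, glia, leukocytes, vessels, fibroblasts, red blood cells, proliferation, metabolism, stress, cell death, ribosomes, mitochondria, synapses and extracellular proteases. List pairs with genes in common shared 1 to 3 genes, and listed symbols that the table lacks were looked up as synonyms, Pirb among them. Other genes in the text were chosen after their values were seen, and some genes that the rule names are not reported here.

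The alternatives were RLE size factors, library totals, upper-quartile scaling, no filter on low counts, a filter of at least 5 CPM in 3 samples, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), the replicate number as a block, leaving out each library, adjusted p under 0.1, and an absolute log2 fold change of at least 1. A test against a 1.5-fold change and a fit without chromosomes X, Y and MT were added after the data were seen.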

Results

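The data were gene-level read counts from 6 libraries of cultured adult mouse DRG neurons, 3 given PBS and 3 given oncomodulin, a calcium-binding protein studied as an axon growth factor. The total count was 64477014, 55920700 and 57440920 in the PBS libraries and 53770820, 60291315 and 56288226 in the ONCM libraries. Between 25936 and 26962 genes had at least 1 count in a library. Mitochondrial genes took 2.89% to 3.06% of the counts with PBS and 2.73% to 2.92% with ONCM. Ribosomal RNA genes took 0.238% to 0.259% with PBS and 0.179% to 0.194% with ONCM, and the 10 most abundant genes took 4.68% to 4.74% and 4.42% to 4.45%, so these shares separated the groups.

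The comparison asked which transcripts differ in the DRG neuron cultures after 12 hours with oncomodulin. Counts were not separated by cell type. With PBS, Schwann cell and myelin genes summed to 4777 CPM, satellite glia genes to 3097 CPM and fibroblast genes to 561 CPM. A change therefore cannot be assigned to neurons from these counts alone. Genes known from injured sensory neurons were among the largest rises. Npy, the neuropeptide Y gene, went from 1.89 ± 0.074 to 165 ± 1.75 CPM (SD, n = 3 per group), a rise of 87.4-fold. Sprr1a, a small proline-rich protein induced in injured neurons, rose 74.2-fold from 10.5 ± 0.233 to 779 ± 51.5 CPM, and the neuropeptide gene Gal rose 27.4-fold from 12.2 ± 0.117 to 335 ± 14.1 CPM. Genes of nociceptor identity went the other way, with the sodium channel gene Scn11a falling from 367 ± 8.21 to 178 ± 2.03 CPM. All 45 tested interferon-stimulated genes rose. In the same libraries the X-linked transcript Xist stood at 0.53 ± 0.053 CPM with PBS and 478 ± 55.8 CPM with ONCM, so that a difference in sex-linked transcripts coincided with the treatment.

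By edgeR's quasi-likelihood test, 9829 of 20354 tested genes (48.3%) changed, 4869 upward and 4960 downward, and 10525 did not pass. Rises were more often large, with 1258 genes raised and 410 lowered at least 2-fold, and 367 raised and 41 lowered at least 4-fold. Of the calls, 3089 had a log2 fold change of less than 0.25 in size. The groups did not overlap for 55.6% of tested genes, against 10% by chance. The share of calls that were rises was 49.5% on counts and 39.2% on log2(TPM + 1), where 3631 genes rose and 5628 fell. The first principal component held 66.5% of the variance and separated the groups. Correlations across genes, which are not independent replicates, were 0.9917 to 0.9929 within groups and 0.9746 to 0.9764 between groups.

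Transcripts of Ocm itself, the gene for oncomodulin, were counted 2 times in 1 PBS library and 4 times in 1 ONCM library and were at 0 in the other 4, too few to test. Armc10, the receptor reported for oncomodulin (chromosome 5, 21646006 to 21662699), rose slightly from 17.1 ± 0.326 to 19.5 ± 0.994 CPM, a log2 fold change of 0.19 (SE 0.06, edgeR adjusted p = 0.0104). The Armc10 call was lost without ONCM replicate 1 (0.16, adjusted p = 0.0563) and on the log2(TPM + 1) scale (0.12, adjusted p = 0.0707).

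Besides Npy (chromosome 6, 49822710 to 49829507) and Sprr1a (chromosome 3, 92483954 to 92485881), the 10 largest rises included genes that were barely counted with PBS. Reg1, a secreted lectin of the regenerating-islet family on chromosome 6, had no count in any PBS library and 2.27 ± 0.238 CPM with ONCM, at least 44.8-fold above a floor of 3 counts per library. Lipn, a lipase gene on chromosome 19, rose from 0.107 to 33.5 CPM (log2 fold change 8.27, SE 0.12). Anxa10, an annexin, and Igfn1, an immunoglobulin-domain protein of muscle, rose by 6.62 and 5.30 on the log2 scale. Slc6a4, the serotonin transporter (chromosome 11, 76998597 to 77032343), rose 39.3-fold from 0.995 ± 0.186 to 39.3 ± 0.192 CPM. The potassium channel gene Kcnk16 rose 38.5-fold to 9.35 ± 0.298 CPM, and Car3, a carbonic anhydrase, rose 29.7-fold to 108 ± 3.59 CPM. For these genes edgeR gave adjusted p-values from 9e-23 for Npy to 2.14e-08 for Xist.

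Falls were smaller. Srd5a2, a steroid 5-alpha-reductase gene, fell by 3.21 on the log2 scale, from 3.29 ± 0.274 to 0.36 ± 0.22 CPM. Comp, the cartilage oligomeric matrix protein, went from 15.9 ± 0.62 to 3.21 ± 0.344 CPM. Htr3a, a subunit of the ionotropic serotonin receptor (chromosome 9, 48899213 to 48911152), fell from 227 ± 0.924 to 62.9 ± 2.93 CPM, a log2 fold change of -1.85 (SE 0.04, edgeR adjusted p = 2.3e-17). Oprk1, the kappa opioid receptor, fell from 2.03 ± 0.32 to 0.536 ± 0.187 CPM. Dnah6, an axonemal dynein chain, and Crybb1, a lens crystallin, fell from 1.96 and 2.26 CPM to 0.487 and 0.571 CPM. Fam205a4, Fam205a3 and Fam205a2 on chromosome 4 had -2.03, -2.02 and -1.97, but these near-identical copies can share reads and their separate values are uncertain. Ddx3y on chromosome Y was the remaining gene of the 10.

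The sex-linked transcripts differed between the groups in all libraries. The labels give female for every sample, yet Ddx3y, an RNA helicase encoded on chromosome Y, stood at 60.5 ± 2.17 CPM with PBS and 16.1 ± 0.933 CPM with ONCM. Uty, Kdm5d and Eif2s3y, also Y-linked, stood at 16.9, 18.4 and 28.8 CPM with PBS and at 31%, 31.4% and 35.7% of those levels with ONCM, and Ddx3y at 26.6%. Ddx3y was alike in the 3 ONCM libraries, at 16.2, 16.9 and 15.1 CPM. These libraries may therefore share 1 pool of cells, which was not tested. Xist, the RNA that coats the inactive X chromosome (X, 103460373 to 103483233), was at most 0.588 CPM in a PBS library and at least 413 CPM in an ONCM library. The X-linked partners Kdm6a, Eif2s3x, Kdm5c and Ddx3x, which escape X inactivation, rose by 0.45, 0.65, 0.38 and 0.34 on the log2 scale. No library of one group matched the other in these genes, so a value within one sex cannot be had. Sex, any other difference between the source cells of the groups, and treatment cannot be told apart for any gene tested. Without chromosomes X, Y and MT, 9471 genes changed. That fit cannot remove an effect of sex or source cells on genes of the other chromosomes.

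**Figure D1:**
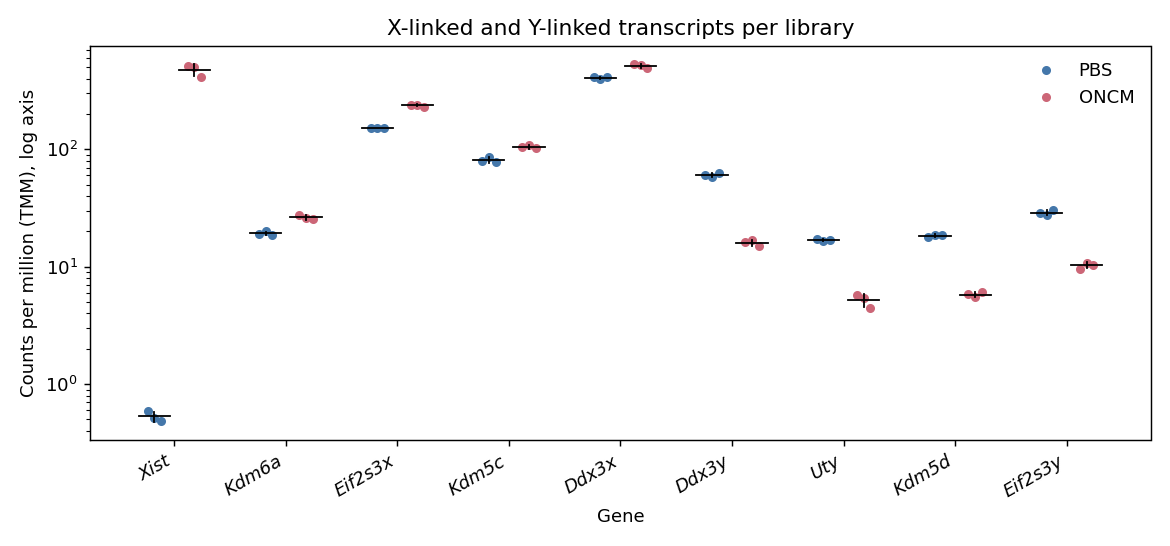
Library-size-scaled counts (CPM, log axis) of Xist, 4 other X-linked genes and 4 Y-linked genes in each PBS and ONCM library, with the group mean and SD (n = 3) as black lines. Xist lies at 0.53 CPM with PBS and 478 CPM with ONCM, and each Y-linked gene is lower with ONCM.

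Of 39 tested regeneration-associated genes, 31 rose, 4 fell and 4 did not pass, with 31 and 4 adjusted over the list alone. Beyond Npy, Sprr1a and Gal, Nts, the neurotensin gene, rose 9.40-fold from 15.1 ± 0.645 to 142 ± 4.4 CPM, and the growth cone protein gene Gap43 rose from 186 ± 3.51 to 520 ± 18.5 CPM. The injury-induced transcription factor genes Atf3, Sox11 and Jun rose less, by 0.67, 0.25 and 0.13 on the log2 scale. Cd9, Smad1, Fxyd7 and Flrt3 fell, and Arg1, L1cam, Klf6 and Tnfrsf12a did not pass. The list's median log2 fold change was 0.85 (limma camera, adjusted p = 2.06e-13, and adjusted p = 0.0485 with an estimated correlation). Among 46 axon growth cytoskeleton genes 24 rose, 11 fell and 11 did not pass (25 and 12 adjusted over the list alone). The tubulin genes Tuba1a, Tubb2b, Tubb2a and Tuba1b rose 2.17-fold, 2.77-fold, 2.41-fold and 1.69-fold, while the kinesin genes Kif5a, Kif5b and Kif3c and the tau gene Mapt fell. The median of that list was 0.19 (camera adjusted p = 0.00981, and adjusted p = 0.145 with an estimated correlation). Growth-restraining genes split, with 4 raised, 12 lowered and 9 not passing of 25 (4 and 12 adjusted over the list alone). Rtn4rl1, a Nogo receptor homologue, and the calcium channel subunit gene Cacna2d2 had log2 fold changes of -0.93 and -0.90, and the guidance receptor gene Plxna4 and the immune receptor gene Pirb rose by 0.77 and 1.74. Camera gave an adjusted p = 0.0416 for a lower list, and adjusted p = 0.311 with an estimated correlation. That call was also lost without ONCM replicate 1 (adjusted p = 0.0636) or ONCM replicate 3 (adjusted p = 0.0691). Xist was 478 CPM in these ONCM libraries and 0.53 CPM with PBS.

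**Figure D2:**
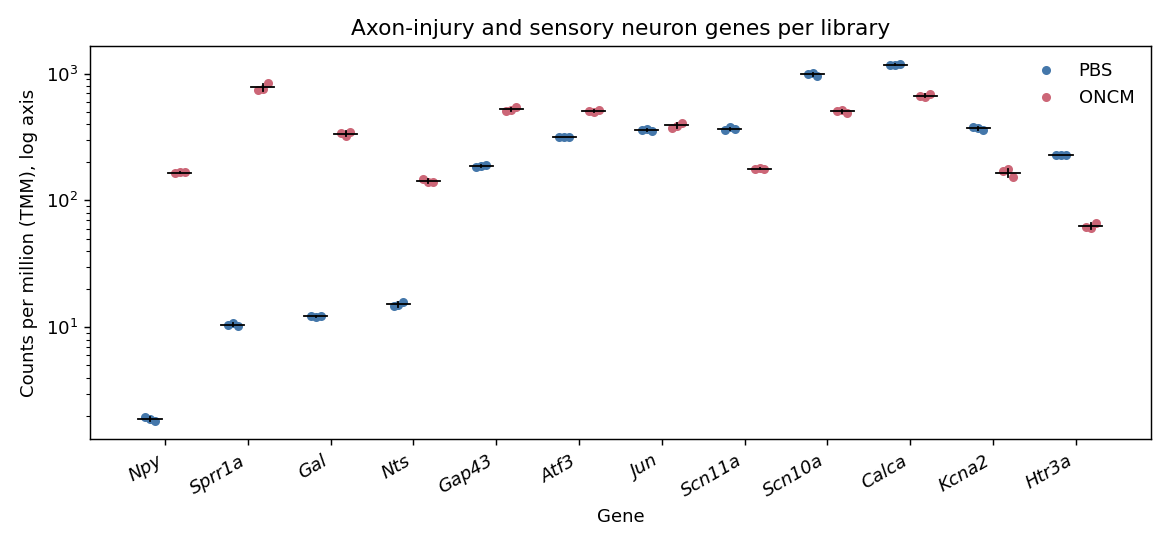
Library-size-scaled counts (CPM, log axis) of 12 axon-injury and sensory neuron genes in each library, with the group mean and SD (n = 3) as black lines. Npy rises from 1.89 to 165 CPM and Htr3a falls from 227 to 62.9 CPM, with no overlap between the groups.

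Of 29 nociceptor genes 25 fell, 4 rose and 0 failed to pass (25 and 4 adjusted over the list alone). The sodium channel genes Scn11a and Scn10a had log2 fold changes of -1.04 and -0.97 (SE 0.03 each), and Calca, which encodes calcitonin gene-related peptide, -0.81 (SE 0.03). Ret, Gfra3, P2rx3 and Il31ra, a pair of neurotrophic factor receptors with a purinergic and an itch receptor, rose. The median was -0.84 (camera adjusted p = 2.69e-08, and adjusted p = 0.0299 with an estimated correlation). Of 25 mechanoreceptor and proprioceptor genes 20 fell, 1 rose and 4 did not pass (20 and 2 adjusted over the list alone). The potassium channel gene Kcna2 fell from 369 ± 9.98 to 166 ± 12.5 CPM, Etv1, a transcription factor of proprioceptors, from 132 ± 3.61 to 70.4 ± 2.22 CPM, and Scn1a from 162 ± 5.5 to 88.7 ± 5 CPM. Spp1, the osteopontin gene, rose 2.10-fold. The list had a median of -0.46 (camera adjusted p = 2.7e-07, and adjusted p = 0.0967 with an estimated correlation). In the ion channel list 25 of 33 genes fell, 4 rose and 4 did not pass (25 and 4 adjusted over the list alone). Kcns3 and Kcnd3, both voltage-gated potassium channel genes, had log2 fold changes of -1.16 and -0.95, and Cacna2d1, the calcium channel subunit bound by gabapentin, rose 3.37-fold to 445 ± 22.0 CPM. Its median was -0.61 (camera adjusted p = 5.76e-07, and adjusted p = 0.0967 with an estimated correlation). Synaptic vesicle genes numbered 15 lowered, 3 raised and 8 not passing of 26 (15 and 4 adjusted over the list alone). Cplx2, Sv2b and Vamp1 fell to 212, 211 and 485 CPM, from 417, 340 and 722 CPM, and Syt4 rose 1.63-fold. Camera gave adjusted p = 0.00183, and adjusted p = 0.321 with an estimated correlation.

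Pan-neuronal genes did not move as 1 group (24 tested, 6 raised, 11 lowered, 7 not passing, and 6 and 11 adjusted over the list alone). Tubb3, a neuronal tubulin, rose 1.74-fold to 3618 ± 169.9 CPM, and Snap25, Rbfox3 and Nefh, for a vesicle fusion protein, a neuronal splicing factor and the heavy neurofilament, had log2 fold changes of -0.53, -0.67 and -0.48. The median was -0.08 (camera adjusted p = 0.123). Neurotrophic genes were evenly divided, with 10 raised, 10 lowered and 2 not passing of 22 (10 and 11 adjusted over the list alone). Gfra1, the receptor for GDNF, rose 1.88-fold to 816 ± 9.16 CPM, Lif, a cytokine of the interleukin 6 family, rose 1.76-fold, and Igf1 and Gdnf rose 2.74-fold and 1.38-fold. The median was -0.16 and the mean -0.03, while camera pointed upward with adjusted p = 0.949. Of 33 cAMP and immediate early genes, 9 rose, 15 fell and 9 did not pass (10 and 15 adjusted over the list alone). Vgf, a neuropeptide precursor, and Dusp1, a phosphatase, rose 1.76-fold and 1.60-fold, and Scg2 and Pde4d had log2 fold changes of -0.74 and -0.54. The median was -0.12 (camera adjusted p = 0.45).

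All 45 interferon-stimulated genes rose (45 adjusted over the list alone), with a median log2 fold change of 1.41 (camera adjusted p = 1.4e-28, and adjusted p = 0.0299 with an estimated correlation). Ifit3, Rsad2, Ifit1 and Ifit3b, antiviral effectors, rose 3.56-fold, 3.19-fold, 2.96-fold and 3.27-fold, with Ifit3 going from 153 ± 3.3 to 547 ± 9.62 CPM. In the NF-kB and cytokine list 40 of 43 genes rose, Steap4 fell, and Il1b and Mmp9 did not pass (40 raised and 1 lowered adjusted over the list alone). The chemokine genes Cxcl1 and Cxcl5 rose from 29.0 ± 0.92 to 109.6 ± 4.04 CPM and from 4.59 ± 0.519 to 30.6 ± 1.88 CPM, the complement gene C3 rose 3.99-fold, and Il1rn, the interleukin 1 receptor antagonist, rose 3.65-fold. The median was 0.86 (camera adjusted p = 1.46e-16, and adjusted p = 0.0309 with an estimated correlation). Macrophage markers rose beside them, 27 of 30, with Lyve1 lowered and Cx3cr1 and Fcgr3 not passing (29 raised and 1 lowered adjusted over the list alone). C1qc and C1qb, subunits of complement C1q, rose 8.50-fold and 4.98-fold to 8.45 ± 0.19 and 13.4 ± 0.522 CPM, the protease gene Ctss 5.07-fold to 22.3 ± 0.252 CPM, and Mpeg1, a pore-forming protein of macrophages, 3.91-fold to 44.5 ± 1.78 CPM. The median was 1.72 (camera adjusted p = 1.76e-13, and adjusted p = 0.0299 with an estimated correlation). Summed over their lists, interferon-stimulated genes went from 2451 ± 29.8 to 5877 ± 84.6 CPM and macrophage markers from 139.7 ± 4.77 to 368 ± 9.76 CPM. These immune genes moved together with Xist, at 0.53 CPM with PBS and 478 CPM with ONCM.

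**Figure D3:**
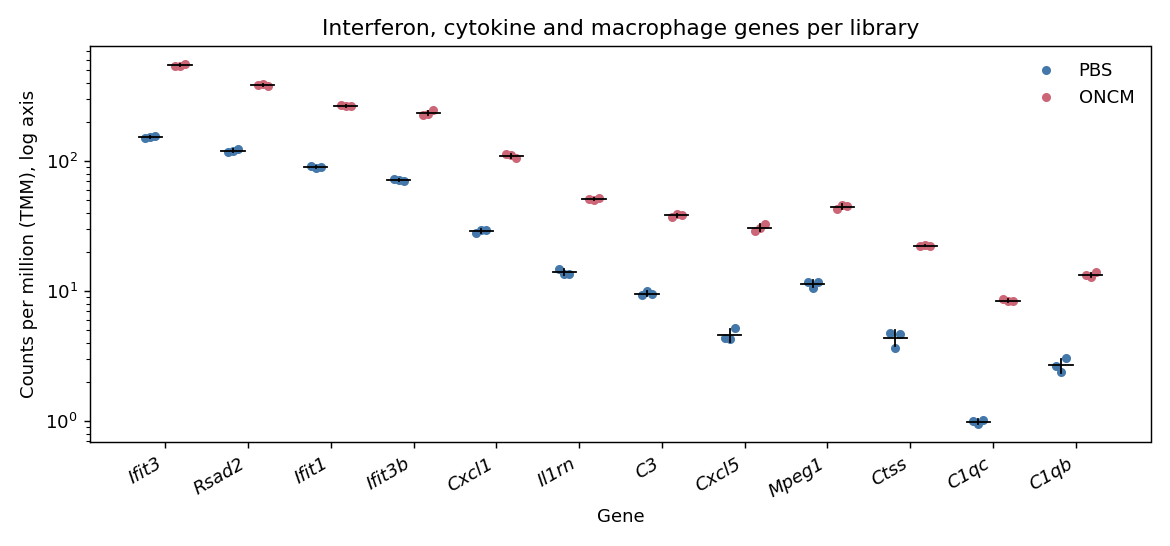
Library-size-scaled counts (CPM, log axis) of 4 interferon-stimulated, 4 cytokine and complement and 4 macrophage genes in each library, with the group mean and SD (n = 3) as black lines. Each gene is higher with ONCM, by 2.96-fold for Ifit1 and 8.50-fold for C1qc.

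Extracellular protease genes rose in 19 of 24 cases, with 2 lowered and 3 not passing (20 and 2 adjusted over the list alone). Adam8, a membrane metalloprotease, rose 5.08-fold from 18.4 ± 0.353 to 93.6 ± 2.5 CPM, Mmp16 and Plau, the urokinase gene, rose 3.47-fold and 2.49-fold, and Adamts1 rose 1.52-fold. The median was 0.42 (camera adjusted p = 3.48e-07, and adjusted p = 0.0309 with an estimated correlation). STAT3 targets and acute-phase genes had 14 raised, 2 lowered and 5 not passing of 21 (15 and 2 adjusted over the list alone). Cebpd, Bcl3, Il4ra and Stat3 itself rose by 0.84, 0.75, 0.51 and 0.35 on the log2 scale, and the list had camera adjusted p = 0.00295, and adjusted p = 0.0967 with an estimated correlation. TGF-beta and BMP targets went both ways, 4 raised, 8 lowered and 9 not passing of 21 (4 and 8 adjusted over the list alone). The matricellular gene Ccn2 and the transcriptional inhibitor genes Id4 and Id2 had log2 fold changes of -0.90, -0.84 and -0.53, Tgfbi rose 1.75-fold, and camera gave adjusted p = 0.533.

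Of 15 satellite glia genes 5 rose, 2 fell and 8 did not pass (5 and 3 adjusted over the list alone), with the glutamine synthetase gene Glul 1.58-fold higher, Hmgcs1 and Atp1b2 raised by 0.39 and 0.29, and Aldoc at -0.32. Their median was 0.03, of the opposite sign on the TPM scale (camera adjusted p = 0.486). Of 25 Schwann cell and myelin genes 7 rose, 5 fell and 13 did not pass (7 and 5 adjusted over the list alone). S100b and Pmp2 had log2 fold changes of -0.38 and -0.72, while Drp2 and Pmp22, of peripheral myelin, rose by 0.26 and 0.22. The median was -0.01 and the mean -0.04, and camera pointed upward with adjusted p = 0.931. Repair Schwann cell genes had 11 raised, 4 lowered and 4 not passing of 19 (11 and 4 adjusted over the list alone), led by Gap43, also a neuronal gene, and by Sema4f, Ucn2 and Ccl2 at 2.61-fold, 2.39-fold and 1.80-fold. Camera gave adjusted p = 0.0224, and adjusted p = 0.118 with an estimated correlation.

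Endothelial genes rose in 13 of 20 cases and 7 did not pass (14 raised adjusted over the list alone). Podxl, Eng, Robo4 and Kdr, of the vessel surface, rose by 0.39, 0.43, 0.56 and 0.40, and camera gave adjusted p = 3.62e-04, and adjusted p = 0.0602 with an estimated correlation. Fibroblast genes had 14 raised, 1 lowered and 8 not passing of 23 (15 and 2 adjusted over the list alone). The proteoglycan genes Dcn and Lum rose 1.77-fold and 1.92-fold, and Clec3b and Itgbl1 rose from 0.505 and 0.621 CPM to 2.65 and 2.10 CPM, with camera adjusted p = 1.52e-04, and adjusted p = 0.107 with an estimated correlation. Of 10 mural genes 3 fell, 1 rose and 6 did not pass (3 and 1 adjusted over the list alone). Rgs5, Pdgfrb and Cspg4 had log2 fold changes of -0.66, -0.43 and -0.16, Abcc9 rose by 0.93, and camera gave adjusted p = 0.45. The globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt all fell, with log2 fold changes of -0.66, -0.66, -0.45 and -0.42, among 6 red blood cell genes of which 2 did not pass (4 lowered adjusted over the list alone). Hba-a1 and Hba-a2, and the Hbb pair, are near-identical copies whose separate values are uncertain. Camera gave adjusted p = 0.00522, and adjusted p = 0.115 with an estimated correlation. Of 13 genes of other leukocytes 4 rose, 3 fell and 6 did not pass (4 and 6 adjusted over the list alone). Of the neutrophil genes, Ly6g and Csf3r rose from 0.136 and 0.627 CPM to 1.88 and 1.44 CPM and Cxcr2 also rose. The neutrophil genes S100a8 and S100a9 did not pass, so these genes did not rise as a set. Kit and Flt3 had log2 fold changes of -0.45 and -0.37. Kit and Flt3 stood at 46.5 and 25.4 CPM with PBS, of 77.4 CPM summed over the list. Whether leukocytes were their source was not tested. The median was -0.03 and the mean 0.37, and camera pointed downward with adjusted p = 0.843. Among 30 proliferation genes 7 rose, 6 fell and 17 did not pass (7 and 6 adjusted over the list alone). Mcm6 and Pcna, of DNA replication, rose by 0.74 and 0.20, E2f1 and Ccnd1 had -0.49 and -0.28, and camera gave adjusted p = 0.459.

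Cholesterol and sterol genes rose in 16 of 22 cases, and 6 did not pass (16 raised adjusted over the list alone). Mvd and Mvk, of the mevalonate pathway, rose 1.81-fold and 1.63-fold, with camera adjusted p = 2.64e-04, and adjusted p = 0.0906 with an estimated correlation. Cytosolic ribosomal protein genes rose in 27 of 32 cases by small amounts, and 5 did not pass (28 raised adjusted over the list alone). Rps3, Rpl8 and Rpl24 rose by 0.36, 0.27 and 0.26, with camera adjusted p = 5.81e-06, and adjusted p = 0.439 with an estimated correlation. Of 28 mitochondrial respiratory chain genes 3 rose, 7 fell and 18 did not pass (3 and 7 adjusted over the list alone). Ndufb3, Ndufb8 and Sdha had -0.35, -0.19 and -0.17, Sdhb rose by 0.24, and camera gave adjusted p = 0.486. Of 33 tested genes on the mitochondrial chromosome, examined after the data were seen, 17 fell and 3 rose, and the ribosomal RNA gene mt-Rnr2 fell from 1622 ± 61.1 to 1162 ± 42.7 CPM. The 13 protein-coding genes among them were split, with 4 lowered, 3 raised and 6 not passing, and COX1, a cytochrome oxidase subunit, rose from 8558 ± 213 to 9043 ± 209 CPM. Hypoxia and glycolysis genes had 12 raised, 9 lowered and 5 not passing of 26 (13 and 9 adjusted over the list alone). The glycolytic genes Pgk1 and Eno1 and the glucose transporter gene Slc2a1 rose 1.47-fold, 1.36-fold and 1.48-fold, and Bnip3 had -0.65. Their median of 0.05 had the opposite sign on the TPM scale (camera adjusted p = 0.381).

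Cell death genes rose in 15 of 22 cases, with 3 lowered and 4 not passing (17 and 3 adjusted over the list alone). Mlkl, the necroptosis effector, rose 2.27-fold, and Hrk, a neuronal death gene, from 0.492 to 2.45 CPM, while the survival gene Bcl2 fell from 45.4 ± 0.936 to 27.2 ± 3.03 CPM. Camera gave adjusted p = 2.07e-04, and adjusted p = 0.0574 with an estimated correlation. Of 18 p53 targets 11 rose, 2 fell and 5 did not pass (11 and 3 adjusted over the list alone). Pmaip1 and Cdkn1a rose 2.83-fold and 1.72-fold, Phlda3 and Plk2 rose by 0.36 and 0.18, and camera gave adjusted p = 0.0516, or 0.0369 without ONCM replicate 1. In the heat shock list 6 of 14 genes fell, 1 rose and 7 did not pass (6 and 1 adjusted over the list alone). The chaperone genes Dnajb1, Hsph1, Chordc1 and Dnaja1 had log2 fold changes of -0.65, -0.50, -0.43 and -0.21. Camera gave adjusted p = 0.046, and adjusted p = 0.313 with an estimated correlation. That call was also lost without PBS replicate 3, ONCM replicate 1 or ONCM replicate 2 (adjusted p = 0.0584, 0.101 and 0.0754). NRF2 and metal genes had 6 raised, 10 lowered and 4 not passing of 20 (6 and 10 adjusted over the list alone), with Srxn1 and the metallothionein gene Mt2 raised 1.44-fold and 1.49-fold, and Gsta4 and Gclm, of glutathione metabolism, at -0.82 and -0.43 (camera adjusted p = 0.459). Unfolded protein and amino acid stress genes had 10 raised, 8 lowered and 8 not passing of 26 (10 and 9 adjusted over the list alone). Mthfd2 and the amino acid transporter gene Slc7a5 rose 1.32-fold and 1.31-fold and the chaperone genes Hsp90b1 and Herpud1 had -0.36 and -0.43, with a median of 0.00, whose sign changed with RLE and upper-quartile scaling, and camera adjusted p = 0.843.

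**Figure D4:**
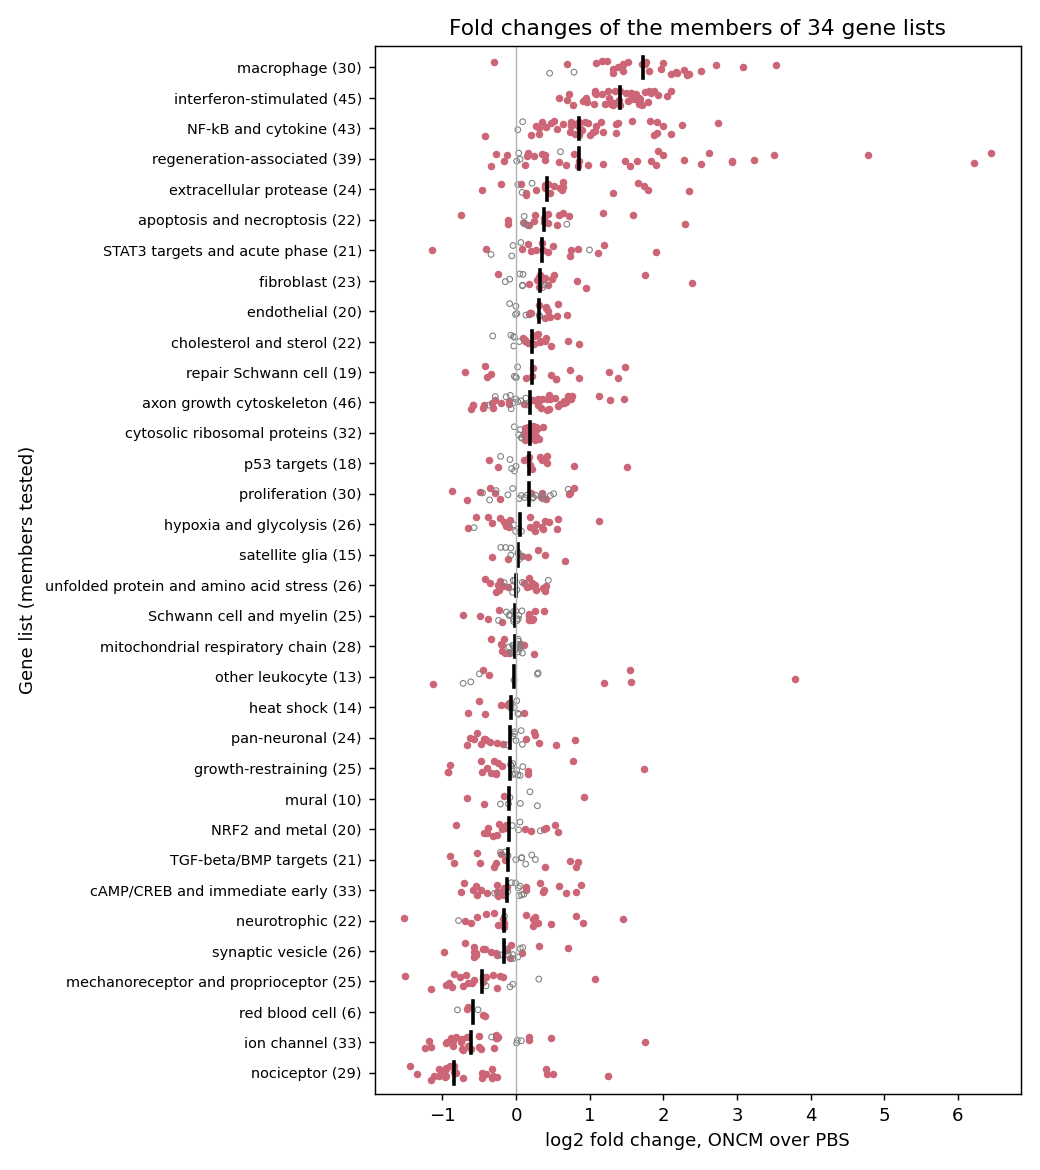
Log2 fold change (ONCM over PBS) of each tested member of 34 gene lists, with filled points for genes that passed, open points for those that did not, and black bars for list medians. Medians run from -0.84 for nociceptor genes to 1.72 for macrophage markers.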

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

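The test against a 1.5-fold change and the fit without chromosomes X, Y and MT were chosen only after the results were seen. Of the 9829 changed genes (4869 raised, 4960 lowered), requiring an absolute log2 fold change of at least 1 left 1668 (1258 raised, 410 lowered), and testing against a 1.5-fold change with edgeR left 1739 (1163 raised, 576 lowered), both because they ask for larger changes. Camera passed 20 gene lists with the preset correlation and 6 with an estimated one, and fry, which tests a different question, passed 29. Some lists lost their camera call although their estimate was below the preset 0.01. Cell death genes (-0.03) went from adjusted p = 2.07e-04 to 0.0574, and endothelial genes (-0.011) from 3.62e-04 to 0.0602. A higher correlation between members does not account for those losses. Other lost lists had higher estimates, up to 0.569 for cytosolic ribosomal protein genes. The count of changed genes was 9801 with RLE size factors, 9838 with library totals, 9791 with upper-quartile scaling, 9582 without a filter, 7486 with the filter of 5 CPM, 8234 with DESeq2, 9831 with limma-voom, 9259 on log2(TPM + 1), 9190 on log2(TPM + 0.1), 11059 at adjusted p under 0.1 and 9471 without chromosomes X, Y and MT. Leaving out each library gave 8752 to 9537 changed genes and 19 to 20 lists, and 7456 of the 9829 calls passed in each of those 6 fits. Among the named genes, Armc10 lost its call in 3 settings (log2 fold change 0.12 on log2(TPM + 1), 0.13 on log2(TPM + 0.1) and 0.16 without ONCM replicate 1), and the cause was not tested. No named gene reversed in any setting run. List tests were repeated only with an estimated correlation, fry, the replicate block and leaving out each library, and no list call reversed there. With the other scalings, filters and tools the list calls were not tested. On log2(TPM + 1), 32 of 34 list medians kept their sign. Of the calls shared with log2(TPM + 1) and log2(TPM + 0.1), 8242 of 8244 and 8222 of 8224 kept their direction, so 2 genes reversed in each. The median of the unfolded protein list changed sign with RLE and upper-quartile scaling.

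Deviations of same-numbered PBS and ONCM libraries had correlations of -0.045, -0.012 and 0.002 across genes, so the numbers gave no sign of pairing. With the replicate number as a block 9597 genes changed and 18 lists passed, with adjusted p = 0.0533 for growth-restraining and 0.0723 for heat shock genes. Genes with the fewest counts, such as Ocm, were left out of the tests. With 3 libraries per group the common biological coefficient of variation was 4.14%.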

Other observations

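Tests of explanations given here were all chosen after the results were seen, except the count over other splits of the samples. The gene families and chromosome regions were picked after their values were seen. Neuropeptide genes changed in both directions, with 11 of 23 raised and 8 lowered. Adcyap1, which encodes the peptide PACAP, rose from 56.4 ± 1.32 to 176 ± 1.71 CPM (SD, n = 3 per group). Ucn and Crh, of the corticotropin-releasing family, rose from 0.148 and 0.732 to 4.31 and 3.70 CPM. Nmb, the neuromedin B gene, fell from 107 ± 7.41 to 35.5 ± 1.35 CPM, and Tac1, the substance P precursor, from 109.9 ± 2.91 to 60.8 ± 0.726 CPM. Serotonin receptor genes mostly fell, 8 of 14, with 2 raised. Htr3b, the partner of Htr3a, went from 29.5 ± 0.874 to 8.89 ± 0.429 CPM and Htr7 from 15.9 ± 0.42 to 7.75 ± 0.476 CPM, while Htr2a rose from 10.03 ± 0.376 to 12.9 ± 1.23 CPM. Serotonin synthesis genes Tph1 and Tph2 did not pass by edgeR (adjusted p = 0.0502 and 0.52).

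Of 84 potassium channel genes 56 fell and 8 rose. Kcnmb1, a subunit of calcium-activated channels, fell from 46.5 ± 2.51 to 16.6 ± 0.698 CPM, and Kcnip3, a channel-interacting protein, from 288 ± 2.46 to 159.9 ± 5.0 CPM, whereas Kcnmb4 rose from 11.8 ± 0.547 to 20.7 ± 1.07 CPM. Nicotinic receptor genes had 8 of 11 lowered, among them Chrna6 at 17.6 ± 0.437 and 5.76 ± 0.581 CPM, and 3 raised. Of 13 Mrgpr receptor genes of itch and pain neurons 9 fell and 1 rose, and Mrgprd went from 57.9 ± 2.74 to 32.2 ± 1.38 CPM. Of 30 Hox genes 15 fell and 2 rose, led by Hoxd1 at 16.8 ± 0.963 and 5.97 ± 0.287 CPM. Tubulin genes rose in 11 of 13 cases and the Trem, Clec and Cd300 receptor genes of myeloid cells in 18 of 21. On chromosome 4 between 41712033 and 42773991, 28 of 37 tested genes fell and 1 rose (median -1.29). On chromosome 5 between 10865029 and 11922804 all 14 tested genes rose (median 2.72), and both regions hold near-identical copies that can share reads. In a further chromosome 5 region, 14910124 to 15657059, all 9 tested genes rose (median 2.55). On chromosome 14 between 69337151 and 69584940, 3 of 4 tested genes fell and 1 rose, with log2 fold changes from -1.51 to 1.61. Shared reads can make copies move alike, whereas the genes in the chromosome 14 region moved in opposite directions. Why the groups differed in these regions was not tested.

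The sex-linked transcripts split the groups completely. Induction of Xist by oncomodulin in female cells was argued against by Y-linked Ddx3y, which was at least 58.1 CPM in each PBS library, and a single mislabelled library by Xist, whose highest PBS value was 0.142% of its lowest ONCM value. Male source animals for PBS and a mixture of sexes for ONCM may account for it, since the ONCM to PBS ratios of 4 Y-linked genes lay within 1.35 times of each other. The ratios were not equal, with log2 fold changes from -1.91 (SE 0.05) for Ddx3y to -1.48 (SE 0.06) for Eif2s3y. A mixture alone would give equal ratios, so it may not be the whole account. A mixture of sexes also goes against the sex given in the labels for every sample, and which animals were used was not tested.

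Of 39 axon-injury and regeneration genes 31 rose with ONCM, with a list median of 0.85 on the log2 scale and far larger rises for a few, such as Npy at 87.4-fold. A higher share of neurons as the only source was argued against, because pan-neuronal markers had a median of -0.08, with 6 of 24 raised and 11 lowered. The largest rise of such a marker was 0.8 on the log2 scale (Tubb3), only just under the 0.85. These markers may themselves change within neurons, so they do not measure the share of neurons. Different sex of the source animals stays open, since 0 PBS libraries held Xist above 1% of the ONCM level and no sex-matched comparison exists. Earlier injury or longer culture of the ONCM cells also stays open, as Atf3, induced by axon injury, was higher by 0.67. An effect of oncomodulin, the difference the design names, cannot be told apart from those possible explanations here.

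Interferon and macrophage genes were both higher with ONCM. More macrophages may be the source of the interferon transcripts: the summed rises were 3426 CPM for interferon genes and 227.9 CPM for macrophage markers, a ratio of 15, but that ratio depends on how abundant the listed genes are, and the content of each in a macrophage was not measured. More macrophages as the source of the macrophage transcripts also stays open, because 27 of 30 markers rose. Their rises were unequal, with 24 of 30 over 2 standard errors from the list median, which goes against a like rise of all markers but could come from unequal baselines in other cells, which were not measured. Endotoxin or another impurity in the recombinant protein stays open too, with 40 NF-kB and cytokine genes raised. Sex, any other difference between the source cells and a response to oncomodulin itself stay open as well.

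Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many changed genes, 9829 against at most 0 in the other splits. The number of splits is too small for a share under 0.05. Every other split also puts PBS and ONCM libraries in the same group, so their difference widens the spread within groups. Low counts there were built in and say nothing on the cause of the changes.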
